A study of Mus musculus with 75 samples.

How the data were processed

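What was measured is messenger RNA in 75 mouse libraries in 37 groups: germ cells sorted from embryos, and PGC-like cells (PGCLCs) grown from embryonic stem cells with or without factors of the female fate. The deposited table holds, per the labels, a signal in RPM for each gene and library, scaled by the authors to the reads assigned to genes, with spike-in values on the same scale beside them. The submitters' processing notes list cutadapt 1.11, TopHat 1.4.1, Bowtie 1.0.1 and Cufflinks 2.2.0 with the mouse build mm10, and the values were used here as deposited. The table has 26218 genes and 96 spike-in transcripts, and each library has its own column. Reads themselves were not analysed here.

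Each value that is a whole number of reads is a multiple of one step, the RPM of a single read. The depth of each library was estimated from that step and checked on its low values with a tolerance of 0.05 reads. Of these low values 81.0 to 93.2 % were whole reads, with the lowest share in the single library named 0R3B. Estimates ran from 1.08 to 15.6 M reads: 2.69 to 4.44 in the embryo, 2.52 to 4.29 in the 129S1:C57BL/6 line, 1.08 to 15.6 in the Stra8 experiment and 2.17 to 4.14 in the C57BL/6 line. The smallest amount taken as measured was 3 reads, and 2777 values above 0 but under 0.001 RPM were set to 0. Libraries with at least 2000 RPM of spike-in transcripts were taken as holding spike-in (58), and the other 17 as without. The E9.5 libraries among the 17 had 475.4 and 1114.3 RPM, and the other 15 had 3.2 to 49.9. The 10 highest genes held 4.38 to 8.49 % of the signal. Counting intervals and floors cover counting error only.

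Values were transformed to log2(RPM + 1), which understates the fold change of genes with low values. A gene was tested where it reached 5 RPM in at least 2 libraries of the experiment: 12567 genes in the embryo, 11873 in the 129S1:C57BL/6 line and 12206 in the Stra8 experiment. Each experiment was fitted on its own with 1 mean per group in limma 3.58.1 under R 4.3.3 (lmFit and eBayes with trend), with 11, 11 and 16 residual degrees of freedom and a median residual SD of 0.27, 0.28 and 0.30. The 21 comparisons were female against male at E12.5, E13.5, E14.5 and E15.5, E15.5 against E11.5 in each sex, RB against CT, RA against CT and RB against RA at days 5, 7 and 9, day 3 against day 0, CT day 9 against day 3, and knockout against wild type at days 3, 5, 7 and 9. A gene was called at a Benjamini-Hochberg adjusted p below 0.05 and an absolute log2 fold change of at least 1. Changes of an effect between stages or days were tested as contrasts of contrasts, for RB against CT (day 9 less day 5), female against male (E15.5 less E12.5) and knockout against wild type (day 9 less day 3).

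There were 15 gene lists with 212 genes: meiotic prophase, pluripotency and early PGC, germ cell and piRNA, male germ cell, oocyte, BMP target, retinoic acid target, DNA methylation machinery, cell cycle, gonadal somatic cell, fibroblast and feeder, somatic lineage, blood and endothelium, stress response, and sex chromosome check. They were written from general knowledge before the data were examined, as were the comparisons, the rule on named genes and 13 alternatives. Lists with at least 3 genes tested were compared with all other genes by camera of limma at a preset correlation of 0.01, and again with the correlation estimated from the residuals. Where the text gives a single adjusted p for a list called at the preset correlation, the call held with the estimated correlation too. Member counts were made at the adjusted p over all genes, and again adjusted over the list alone. Where no second count is given the counts were the same.

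Genes named in the text follow a rule. Stra8 is always named. In the 6 main comparisons (female against male at E14.5, female E15.5 against E11.5, RB against CT, RA against CT and RB against RA at day 9, and knockout against wild type at day 9) the 10 called genes with the largest change each way are named, among those with a mean of at least 20 RPM in the higher group and no overlap between libraries, leaving out predicted names. In the other comparisons the number is 3 each way. In each list up to 4 called members with the largest change are named, and members not called where a count is described. The text leaves out many of the list members the rule allows, and a few genes the rule names are not reported here.

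Genes called at day 9 for RB against CT, and at E14.5 between the sexes, were used as lists in the other experiments. Resemblance between PGCLC and embryo groups was measured as Spearman rho over the 10266 genes called in any of the embryo comparisons. X-linked genes were compared with 10000 random sets drawn from X-linked and autosomal genes together, matched in 20 expression bins. The 7 single libraries were compared as values. Percentiles of their list medians among 10000 random lists matched on expression compare genes within 1 library and say nothing on the spread between libraries. In groups of 4, the gap of the highest or lowest library to its neighbour was compared with the group's range, on log2(RPM + 1), for 88 combinations of gene and group. Intervals of medians in the tests of explanations are 95 % intervals from 2000 bootstrap draws. The model was tested on simulated data with the groups and depths of each experiment: 100 % of genes changed 4-fold were called, and 50, 47 and 44 % of genes changed 2-fold, a change that sits on the threshold. Of unchanged genes 10, 6 and 32 were called, and 0 of those at 20 RPM or more. Every simulated gene had the same CV (10.1, 12.4 and 12.5 %), the median of highly expressed genes, and libraries were drawn independently. Genes of larger spread and deviations shared between libraries were not simulated, so these rates need not hold for the real data.

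Alternatives were log2(RPM + 5), no expression filter, a filter at 20 RPM, quantile normalization, median centring, thinning to the shallowest library, all 75 libraries in 1 fit, only the groups compared, an estimated correlation, lists at an absolute log2 fold change of at least 2, the mean of the SK1 libraries, only libraries without spike-in, only libraries of at least 1.5 M reads, the spike-in as a term, a block by replicate number, other measures of resemblance, and leaving out each library in turn. Of these, 4 were chosen after seeing the data, and the part on the processing names them. No label says that equal replicate numbers share a culture, so no comparison was paired. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 prepared the table and the figures.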

Results

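The series holds 75 mouse libraries made by SC3-seq, a method that sequences the 3' ends of transcripts from small inputs, each amplified from 1 ng of RNA. Embryo germ cells (22 libraries, 11 groups of 2) were sorted by a reporter at E9.5, E10.5 and E11.5 without a sex label, and as female and male from E12.5 to E15.5. The reporter was Dppa3-EGFP up to E13.5 and Ddx4-RFP from E14.5, so across that step reporter and stage cannot be told apart. PGC-like cells derived from embryonic stem cells (PGCLCs) were taken on the day they went into culture and after 3, 5, 7 or 9 days on feeder cells. The 129S1:C57BL/6 line gave 11 groups of 2 libraries: day 0, CT day 3, and CT, RA and RB at days 5, 7 and 9. The labels say that factors inducing the female fate were given from culture day 3, and do not spell out CT, RA or RB, which stand here as group names. The DBA/2:C57BL/6 experiment gave wild type (n = 2) and Stra8 knockout (n = 4, from the lines SK1, SK2 and SK3, with 2 libraries of SK1) at CT day 3 and at RB days 5, 7 and 9. The 7 single libraries, one named 0R3B and 6 of a C57BL/6 line, are in no tested comparison. The C57BL/6 libraries include CT and RB at day 2, named c0CT and c0RB, and at day 9, named c7CT and c7RB. A library of day 2 cannot have had factors from day 3, so RB in this line may differ in start and length from the other lines. The labels do not spell out c0 or c7. Estimated depth ran from 1.08 to 15.6 M reads (median 3.12), so 3 reads correspond to 0.192 to 2.78 RPM, and 13110 to 17298 genes were above 0 in a library. Replicates correlated with Pearson r of 0.978 to 0.993 over all genes. Values below are mean RPM ± SD, with n = 2 libraries per group and n = 4 for the knockout. A gene is called, and said to have risen or fallen, at adjusted p < 0.05 with an absolute log2 fold change (of RPM + 1) of at least 1. How called genes split into higher and lower follows the scaling, so the splits under other scalings are given beside them. The labels do not say whether replicates came from separate cultures or animals, so the p-values measure only the spread between these libraries.

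Stra8, the gate to meiosis in the female germ line (Entrez 20899, chromosome 6 from 34920163 to 34939344), was at 0 in all embryo libraries from E9.5 to E11.5. In females it stood at 38.0 ± 4.70 RPM at E12.5, 313 ± 13.7 at E13.5, 698 ± 80.7 at E14.5 and 303 ± 148 at E15.5, and in males it stayed between 1.62 ± 0.495 and 7.15 ± 2.01. In PGCLCs of the 129S1:C57BL/6 line under CT it was 0.183, 1.82 ± 0.491 and 7.42 ± 0.945 at days 5, 7 and 9. Under RA the same days gave 37.9 ± 10.6, 502 ± 169 and 1094 ± 162, and under RB 56.2 ± 16.5, 1023 ± 234 and 1447 ± 299. In the Stra8 experiment the wild type reached 192 ± 1.35, 1427 ± 17.2 and 1765 ± 68.3 at days 5, 7 and 9, and the knockout 6.98 ± 4.11, 74.2 ± 86.6 and 197 ± 192. The labels do not give the deleted part of Stra8, and a 3' read outside that part would still be counted, so the remaining signal checks nothing about the deletion.

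**Figure D1:**
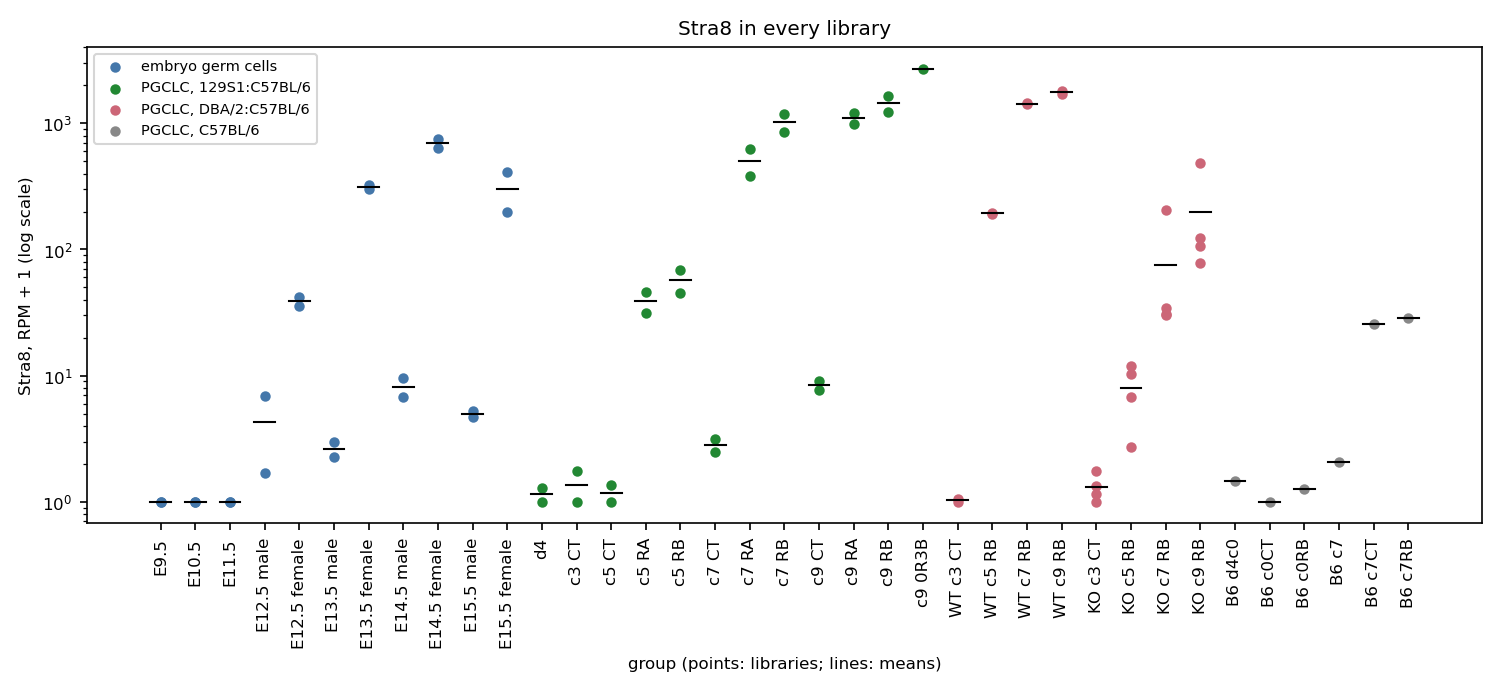
Stra8 in every library, as RPM + 1 on a log scale, with lines at the group means. RB at day 9 averages 1447 RPM and CT 7.42 RPM.

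At E14.5, female germ cells carried meiotic transcripts that male germ cells nearly lacked, and males carried genes of the arrested male germ line that females nearly lacked. Mei1, needed for meiotic double-strand breaks, was at 128 ± 10.9 RPM in females and 0.444 ± 0.224 in males. Ccdc79 (Terb1), which ties telomeres to the nuclear envelope, was at 142 ± 2.37 and 1.01 ± 0.999. On the male side Nanos2, the RNA-binding switch of the male fate, was at 102 ± 16.9 against 0.137 ± 0.194, and Dnmt3l, cofactor of de novo methylation (Entrez 54427, chromosome 10 from 78042287 to 78063622), at 350.2 ± 41.1 against 0.421 ± 0.179 (log2 fold change -7.95, adjusted p = 3.27e-14). Of 12567 genes tested, 2813 were higher and 3252 lower in females (2864 and 3220 with median centring, 3108 and 3079 with quantile normalization). The largest increase was Inca1, an inhibitor of cyclin-dependent kinase (Entrez 103844, chromosome 11 from 70688361 to 70700285), at 432 ± 9.68 against 2.73 ± 3.01 (log2 fold change 7.14). Spdya, an activator of the same kinases, stood at 277 ± 18.3 against 4.35 ± 2.74, and 4930528F23Rik (Meiob), a single-strand DNA binder of meiosis, at 209.7 ± 3.72 against 1.90 ± 0.551. BC051142 (125 ± 17.7 against 0.143 ± 0.202), D6Mm5e (1045 ± 8.75 against 14.6 ± 2.77) and the antisense transcript Msx1as (72.0 ± 8.55 against 0.151 ± 0.213) rose as well. The antigen-presentation genes H2-K1 (833 ± 42.1 against 8.02 ± 2.40) and H2-Ab1 (128 ± 20.8 against 1.02 ± 0.169) were among the largest increases. H2-K1 (Entrez 14972, chromosome 17 from 33996012 to 34000619) has close relatives in its family, so its reads are uncertain. Spocd1, a piRNA-guided methylation factor (217 ± 5.22 RPM), the dynein regulator Ccdc164 (139 ± 1.86) and Vwf of clotting (98.9 ± 6.88) were measured in males and at 0 in females, and Rrad, a small GTPase, stood at 324 ± 0.955 in males against 0.274 ± 0.387. Piwil4, the nuclear piRNA effector (269.8 ± 0.290 against 1.27 ± 0.135), Egr4, a transcription factor of spermatogenesis (251 ± 40.8 against 1.77 ± 2.50), the membrane repair gene Myof (175 ± 10.9 against 0.884 ± 1.25) and Igh (105 ± 7.63 against 0.137 ± 0.194) were also lower in females. Igh stands for a locus of many similar segments, so its identity is uncertain.

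In the meiotic prophase list, 29 of 32 genes tested rose in E14.5 females and 1, Mnd1 (40.5 against 136 RPM), fell, with the same counts adjusted over the list alone (median log2 fold change 3.25, camera adjusted p = 6.79e-14). All 15 genes of the male germ cell list fell (median -4.04, adjusted p = 7.19e-09), Nanos3 of germ cell survival among them (0.137 ± 0.194 against 57.6 ± 6.30). Of 16 pluripotency and early PGC genes 12 fell and 1 rose. They included Dppa4 (21.3 ± 4.90 against 1105 ± 12.9), Utf1 (28.6 ± 7.08 against 647 ± 54.5), Tcl1 (2.71 ± 0.339 against 73.7 ± 5.24) and Dppa3 (115 ± 48.0 against 2019 ± 67.1), and the list's adjusted p was 1.9e-05, or adjusted p = 0.0935 with an estimated correlation. BMP targets rose in 6 genes and fell in 1 of 12 (adjusted p = 0.0711), with Id1, the direct target of BMP signalling (Entrez 15901, chromosome 2 from 152736251 to 152737410), at 229 ± 28.6 against 6.66 ± 3.36, and Id3 at 288 ± 17.9 against 9.68 ± 0.0533. In the oocyte list 3 of 8 genes rose, among them Figla (152 ± 13.2 against 5.24 ± 2.29) and Sohlh2 (142 ± 23.5 against 9.42 ± 2.01), and 3 fell, among them Sohlh1 (1.1 ± 1.15 against 88.9 ± 12.9). That list's median was 0.73 and its mean -0.005. Of 8 DNA methylation genes 5 fell, with Dnmt3a, a de novo methyltransferase, at 12.3 ± 0.0303 against 296 ± 23.5. The cell cycle list was split (6 rose and 3 fell of 17), with the proliferation antigen Mki67 at 192 ± 14 against 12.8 ± 3.59 and the mitotic cyclin Ccnb1 at 35.2 ± 11 against 171 ± 5.31. Retinoic acid targets (1 rose and 3 fell of 8), stress response (1 and 3 of 8) and somatic lineage genes (1 and 1 of 6) gave adjusted p between 0.657 and 0.885. Germ cell and piRNA genes (3 rose and 7 fell of 19) and fibroblast genes (4 fell of 9) did not pass as lists either (adjusted p = 0.411 and 0.167). The 4 blood and endothelium genes gave no call. No gene of the sex chromosome check list passed the expression limit in the embryo.

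The sexes parted in steps, with BMP targets and the Nodal targets Lefty1 and Lefty2 apart at E12.5 and the meiotic list from E13.5. Female cells at E12.5 carried Phlda2, an imprinted growth regulator (468 ± 47.6 against 6.83 ± 1.4 RPM), Id1 (210.3 ± 14.7 against 5.82 ± 2.45), Gata2 (163 ± 2.84 against 10.4 ± 4.20) and Rec8, the meiotic cohesin (53.7 ± 4.68 against 4.16 ± 2.00). Male cells carried Lefty2 (249 ± 1.57 against 1.55 ± 2.2) and Lefty1 (203 ± 3.10 against 2.24 ± 0.769). Of BMP targets 7 of 12 rose, 8 adjusted over the list alone (adjusted p = 2.93e-10), and of retinoic acid targets 3 of 8 rose, 5 adjusted over the list alone (adjusted p = 0.00116). In the male list 7 of 15 fell (adjusted p = 4.74e-05), while the meiotic list had 2 of 32 genes higher and no call (adjusted p = 0.521). By E13.5 the meiotic list had 16 genes higher (adjusted p = 2.05e-08) and the male list 8 lower, Nanos2 at 0.160 ± 0.227 against 30.7 ± 0.183 among them. Msx2, a BMP target, was then at 63.7 ± 30.1 against 0.164 ± 0.232. At E15.5 the counts were 28 higher and 1 lower in the meiotic list, and 15 lower in the male list. Fibroblast genes were lower in 7 of 9 (median -1.36, adjusted p = 0.0602) and gonadal somatic genes lower in 4 and higher in 1 of 8 (adjusted p = 0.426). Prdm9, which places meiotic breaks, stood at 111 ± 13.0 against 0.735 ± 0.00833. Pou5f1, the core pluripotency factor, was at 9.73 ± 0.417 against 272 ± 32.5, with 12 of 16 pluripotency genes lower (adjusted p = 3.92e-06, or adjusted p = 0.0668 with an estimated correlation). Called genes numbered 820 at E12.5, 2101 at E13.5, 6065 at E14.5 and 6737 at E15.5. The sex difference itself changed between E12.5 and E15.5 for 6277 genes, Dnmt3l (log2 difference -9.25) among them. The sorting reporter changed between E13.5 and E14.5, so the rise across that step cannot be given to stage alone. The E12.5 count fell to 544 without male replicate 2 and to 504 without female replicate 2. X-linked genes (534) lay above autosomal genes in the female to male ratio by a median log2 of 0.25, 0.52, 0.40 and 0.33 from E12.5 to E15.5, beyond 100 % of 10000 random gene sets each time. In male samples Cyp17a1 and Cyp11a1, of steroid synthesis in somatic cells of the testis, were at 17.1 ± 11.6 and 13.6 ± 5.49 RPM at E14.5 and at 0 in females. In the gonadal somatic cell list 5 of 8 genes fell at E14.5, 4 adjusted over the list alone (adjusted p = 0.243), and 4 at E13.5 (adjusted p = 0.00851, or adjusted p = 0.0633 with an estimated correlation).

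Along development, E15.5 female germ cells had much higher meiotic transcripts than E11.5 cells and lower pluripotency and early PGC genes. Sycp3, the axial element of the synaptonemal complex (Entrez 20962, chromosome 10 from 88459587 to 88473236), went from 11.1 ± 4.35 to 2521 ± 12.6 RPM (log2 fold change 7.75, adjusted p = 5.82e-18). Sycp1, its transverse filament, went from 3.72 ± 2.54 to 737 ± 23.9, and Taf7l, a germ cell TFIID subunit (Entrez 74469, X chromosome from 134460116 to 134476505), from 0.817 ± 0.701 to 1174 ± 12.8. Zfp541, a spermatocyte chromatin factor, reached 232 ± 11, Zfp672 274 ± 37.1, Spdya 351 ± 9.01 and 4930528F23Rik 262 ± 4.29, each from below 0.5 RPM. Inca1 (554 ± 16.4), Tex16 (290.1 ± 16.1), Stra8 (303 ± 148) and Rad51ap2 (215 ± 28.9; Entrez 209550, chromosome 12 from 11456023 to 11463153), were at 0 at E11.5. Tex16 belongs to a family of near copies on the X, so its reads are uncertain. Nanog went from 138 ± 1.97 to 0. Dppa3 dropped from 2736 ± 82.1 to 24.6 ± 18.6, Utf1 from 784 ± 58.6 to 6.16 ± 1.62, and Tfap2c, a PGC specifier, from 121 ± 14.1 to 0.583 ± 0.0366. Gdf3 of Nodal signalling (199.6 ± 6.89 to 0.443 ± 0.233), Ckb of energy storage (482 ± 9.19 to 3.05 ± 0.0140), Plcd1 (196 ± 12.9 to 0.900 ± 0.879), Sox15 (125 ± 4.23 to 0.278 ± 0.394) and the threonine dehydrogenase Tdh (405 ± 0.757 to 3.81 ± 1.06) were also among the largest decreases. Of 12567 genes 3535 rose and 3077 fell (3344 and 3262 with median centring, 3232 and 3245 with quantile normalization). Meiotic genes rose in 30 of 32 (adjusted p = 1.26e-15), all 16 pluripotency genes fell (adjusted p = 1.21e-11), 16 germ cell and piRNA genes rose and none fell (adjusted p = 1.64e-08), and 12 of 17 cell cycle genes fell and 1 rose (adjusted p = 3.11e-06). Tex15 of transposon silencing (34.0 ± 1.32 to 1425 ± 51.6) and Mael of the piRNA path (46.0 ± 9.77 to 929 ± 28.5) belong to the third of these lists, and Aurkb of the mitotic spindle (133 ± 1.32 to 1.03 ± 0.270) to the fourth. BMP targets gave 3 higher and 5 lower (median 0.34, mean -0.17), and DNA methylation genes 2 and 2 (median 0.53, mean -0.12).

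Male cells took another course over the same stages. From E11.5 to E15.5, Dnmt3l went from 0 to 720.1 ± 115 RPM, the RNA helicase Tdrd9 of the piRNA path from 0 to 328 ± 49.0, Nxf2, an X-linked RNA exporter with near copies, from 0.262 ± 0.371 to 809 ± 4.80, Rrad from 0.131 ± 0.186 to 429 ± 58.0 and Piwil4 from 1.27 ± 0.433 to 396 ± 0.404. All 19 germ cell and piRNA genes rose (adjusted p = 3.64e-13), and 14 of 17 cell cycle genes fell (adjusted p = 7.73e-12), the mitotic kinase Plk1 from 114 ± 6.69 to 13.8 ± 3.54. Meiotic genes rose in 20 and fell in 2 (adjusted p = 0.00042, or adjusted p = 0.0893 with an estimated correlation), to far lower levels than in females, Sycp3 to 199 ± 5.33 and Sycp2 to 89.8 ± 2.27. Called genes numbered 3595 higher and 2324 lower, a majority that turned with quantile normalization (2920 and 3116) and held with median centring (3141 and 2717). Pluripotency genes fell in 11 and rose in 1 of 16 (adjusted p = 9.72e-06, or adjusted p = 0.0606 with an estimated correlation). Markers of other cells moved as well: gonadal somatic genes rose in 5 of 8 (median 2.19) and fibroblast genes rose in 6 and fell in 3 of 9 (median 2.71), without a list call (adjusted p = 0.0776 and 0.681). Over all genes the median log2 fold change was 0.21 in this comparison and -0.14 between the sexes at E15.5, and list medians are to be read against such shifts. Of the blood genes, the embryonic globins Hbb-y and Hba-x were at 1767 ± 61.5 and 835 ± 55.9 at E9.5 and at 83.9 and 48.9 at E10.5, and Hba-a1, which has a near-identical copy, was at 132 ± 108 in E15.5 females and 138 ± 57.9 in E15.5 males.

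**Figure D2:**
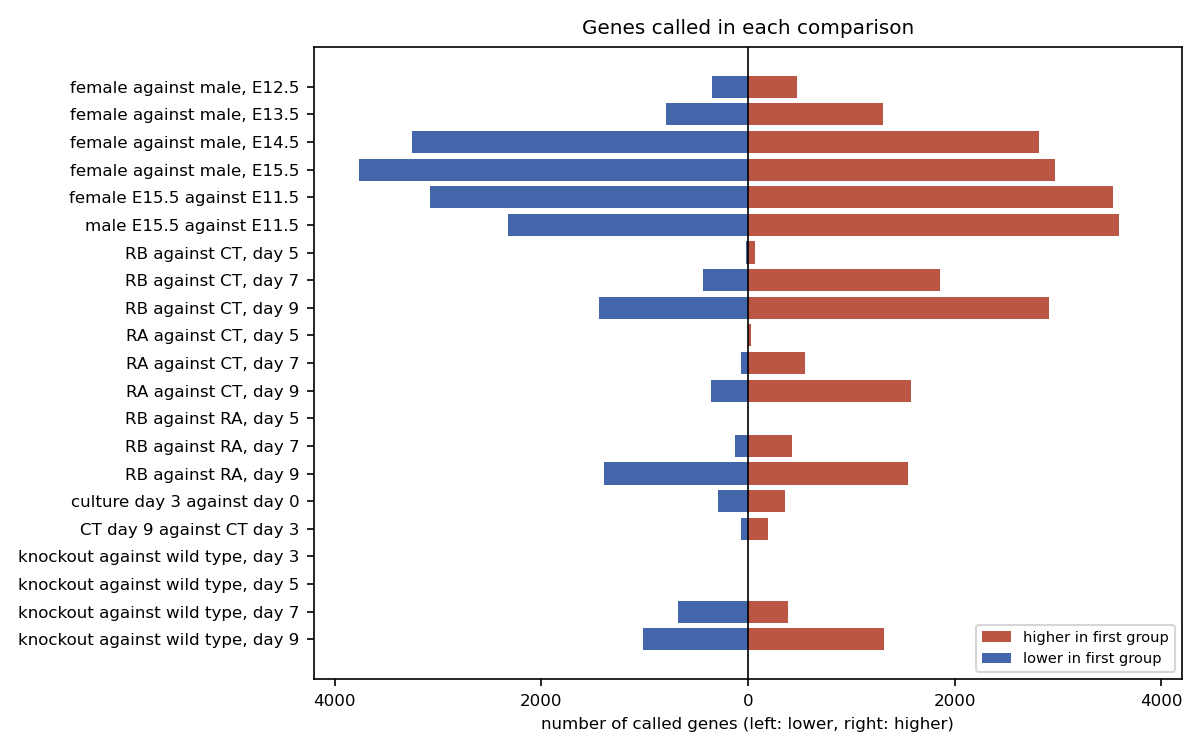
Called genes in the 21 comparisons, lower to the left and higher to the right. The count rises from 820 at E12.5 to 6737 at E15.5 between the sexes, and from 80 to 4354 for RB against CT between days 5 and 9.

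In the first 3 days of culture PGCLCs lost BMP target transcripts and gained early germ cell genes. Id1 dropped from 56.6 ± 2.94 to 6.44 ± 0.271 RPM and Id2 from 24.5 ± 6.44 to 6.64 ± 1.02, while Dazl, the germ cell RNA-binding protein, went from 5.15 ± 2.67 to 42.8 ± 1.47 and Dppa4 from 62.9 ± 8.04 to 265 ± 4.54. Of 18 germ cell and piRNA genes 12 rose and none fell, 13 and 1 adjusted over the list alone (adjusted p = 1.22e-19), and 6 of 12 BMP targets fell (adjusted p = 8.69e-06). The meiotic list had 8 higher and 1 lower, 9 and 2 adjusted over the list alone, with Smc1b, a meiotic cohesin, at 36.4 ± 3.47 against 8.05 ± 1.43 (adjusted p = 7.05e-05, or adjusted p = 0.0786 with an estimated correlation). Lhx1 (40.6 ± 2.03 against 4.09 ± 1.68) and Rpl39l (65.6 ± 33.3 against 1.82 ± 0.501) rose and Prtg (16.2 ± 4.24 against 141 ± 6.63) and Fndc3c1 (0.789 ± 0.186 against 35.8 ± 1.20) fell. Msx1as fell from 33.9 ± 0.224 to 0. Rpl39l resembles its parent gene, so its reads are uncertain. The collagen gene Col3a1 (32.2 ± 9.22 against 0.147 ± 0.207) and Dcn (15.3 ± 0.244 against 0) were called higher after the cells sat on feeder cells. Of 9 genes of the fibroblast list 2 were higher and 1 lower, 3 and 2 adjusted over the list alone, without a list call (median 0.03, adjusted p = 0.396). In all 649 genes were called, and 346 without replicate 2 of day 0. From day 3 to day 9 under CT the cells changed little, with 267 genes called. That count fell to 116 and 163 without CT day 3 replicates 1 and 2, and to 155 and 104 without CT day 9 replicates 1 and 2. Dazl went on to 235 ± 40.3 RPM and Slc6a8, a creatine transporter, to 24 ± 4.89 from 4.08 ± 2.05, while Hmgn5 (363 ± 87.9 to 78.5 ± 0.335), Etv4 (32.9 ± 10.3 to 6.13 ± 2.31) and Efcab10 (45.9 ± 8.11 to 4.83 ± 3.63) fell. The germ cell and piRNA list, at 1 gene higher and 2 adjusted over the list alone (adjusted p = 0.00312), gave adjusted p = 0.332 with an estimated correlation.

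By day 9 of RB, meiotic, BMP target and retinoic acid target genes had risen and pluripotency genes had fallen. Against CT, Tex101, a germ cell surface protein (Entrez 56746, chromosome 7 from 24668012 to 24672050), was at 702 ± 73.9 against 0.323 ± 0.457 RPM (log2 fold change 9.09, adjusted p = 1.54e-14), Taf7l at 929.8 ± 193 against 0.969 ± 0.916 and Sycp2, an axial element protein, at 504 ± 62.7 against 0.483 ± 0.226. Id1 stood at 315 ± 34.7 against 4.19 ± 0.893 and Cyp26a1, the retinoic acid hydroxylase (Entrez 13082, chromosome 19 from 37697738 to 37701536), at 211 ± 23.3 against 4.52 ± 3.67. Of 11873 genes 2915 rose and 1439 fell, an excess of increases that was absent with median centring (2137 and 2266) and quantile normalization (2103 and 2378). Sycp1 (482 ± 61.3 against 1.29 ± 0.906), Tex12 of the central element (379 ± 34.3 against 1.94 ± 0.464) and Nxf2 (156 ± 17.6 against 0.323 ± 0.457) were among the largest increases. Rad51ap2 (182 ± 8.98), the transketolase Tktl1 (213 ± 29.9) and Tex16 (143 ± 15.8) were at 0 under CT. Tdgf1, the Nodal co-receptor (0.537 ± 0.759 against 32.9 ± 0.310), Nr0b1 (0.601 ± 0.288 against 24 ± 0.790), Mup6 (3.39 ± 1.38 against 64.6 ± 6.78), Khdc1a (1.59 ± 1.12 against 27.3 ± 2.27) and Cpsf4l (9.39 ± 0.759 against 109.8 ± 1.17) fell most. Mup6 and Khdc1a have near-identical copies, so their identity is uncertain. Tdh (35.8 ± 13.9 against 356 ± 3.66), the potassium channel Kcnk1 (3.93 ± 0.623 against 48.3 ± 4.80), Nanog (20.2 ± 2.17 against 209.9 ± 31.5), Klf2 (10.6 ± 8.10 against 97.1 ± 9.09) and Fut9, which makes the SSEA1 antigen (1.4 ± 0.296 against 21.8 ± 2.41), complete the 10 largest decreases.

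Meiotic genes rose in 29 of 31 at day 9 of RB (median 4.79, adjusted p = 3.53e-18), germ cell and piRNA genes in 16 of 18 (adjusted p = 1.02e-10), BMP targets in 8 of 12 (adjusted p = 0.00014) and retinoic acid targets in 10 of 13 (adjusted p = 0.000215). Pluripotency genes fell in 15 and rose in 1 of 17 (adjusted p = 5.17e-15), Esrrb from 215 ± 12.7 to 22.6 ± 5.06. In the male list 7 of 13 fell, Lefty1 among them (26.5 ± 4.87 against 144 ± 1.89), and 2 rose, with adjusted p = 0.00641, or adjusted p = 0.105 with an estimated correlation. In the oocyte list 4 rose and 1 fell of 5, with Figla at 46.0 ± 2.86 against 1.93 ± 1.36, Zglp1, an oogenic transcription factor, at 45.9 ± 7.12 against 2.10 ± 0.237, and adjusted p = 0.0488 (adjusted p = 0.235 with an estimated correlation). Cell cycle genes fell in 5 of 17, such as Ccnb1 (164 ± 20.8 against 515 ± 42.6), and fibroblast genes in 4 of 9, such as Vim (42.6 ± 4.31 against 146 ± 8.47). The fibroblast list gave adjusted p = 0.0137, or adjusted p = 0.31 with an estimated correlation. Stress response genes gave 1 call of 7 (median 0.01, mean 0.26, camera direction lower).

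The response built up from day 5. At day 5 of RB, 80 genes were called. Of these 34 and 21 stayed called without RB replicates 1 and 2, and 26 without CT replicate 2. Stra8 (56.2 ± 16.5 RPM), Cyp26a1 (40.5 ± 10.4 against 0.183 ± 0.259), Acp5 (20.9 ± 1.85 against 1.23 ± 0.852) and Id1 (37.5 ± 9.80 against 4.01 ± 0.998) were already higher. BMP targets rose in 3 genes, 4 adjusted over the list alone, and retinoic acid targets in 5, 6 adjusted over the list alone (adjusted p = 3.02e-11 and 4.65e-11). At day 7, with 2292 genes called, meiotic genes rose in 27 of 31, retinoic acid targets in 12 of 13 and BMP targets in 8 of 12, with Fut4 at 74.3 ± 4.62 against 0.277 ± 0.0454. The change between the day 5 and the day 9 response was itself called for 3530 genes, with Tex101 at a log2 difference of 9.55, Nanog at -3.39 and Cyp26a1 at 0.31 (not called). The median of all genes lay at 0.22 and 0.19 for RB at days 7 and 9, and at 0.10 and 0.20 for RA.

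Under RA, retinoic acid targets and Stra8 rose strongly, Sycp1 and Sycp2 rose to modest levels, and BMP targets as a list did not pass. At day 9, RA against CT put Cyp26a1 at 504 ± 23.1 against 4.52 ± 3.67 RPM, Dhrs3, a retinaldehyde reductase, at 64.4 ± 9.92 against 0.161 ± 0.227, Cyp26b1 at 62.9 ± 13.6 against 0.321 ± 0.454 and Stra8 at 1094 ± 162 against 7.42 ± 0.945 (log2 fold change 7.02, adjusted p = 7.97e-14). Sycp1 reached 53.2 ± 0.136 and Sycp2 22.3 ± 4.81. Rec8 reached 178 ± 31.1 from 15.8 ± 1.30, and Taf7l 69.4 ± 10.9. In all 1578 genes rose and 356 fell (1052 and 670 with median centring, 861 and 815 with quantile normalization). Arg1 of the urea cycle (51.9 ± 13.2 against 0.807 ± 0.687), Rgs10 (52.3 ± 2.23 against 0.806 ± 0.232), the myelin gene Pmp22 (130.5 ± 21 against 4.36 ± 2.53) and Dmrtb1, which times the entry of male germ cells into meiosis (26.4 ± 0.566 RPM, with 0 under CT), were among the largest increases. Tdgf1 (2.65 ± 0.265 against 32.9 ± 0.310), the junction gene Jam2 (2.22 ± 0.429 against 24.3 ± 2.86), Gstk1 (2.51 ± 0.458 against 23.9 ± 0.106), Tdh (55.0 ± 14.0 against 356 ± 3.66), Fut9 (3.02 ± 1.15 against 21.8 ± 2.41), the Notch target Hey1 (13.2 ± 0.491 against 81.3 ± 13.6), Tubb3 (5.98 ± 0.437 against 38.9 ± 4.05), Rps6kl1 (6.18 ± 0.618 against 36.8 ± 0.163), Usp43 (4.99 ± 3.19 against 27.9 ± 0.104) and Zfp296 (11.9 ± 2.54 against 64.3 ± 0.854) were the 10 largest decreases. Retinoic acid targets rose in 11 and fell in 1 of 13, with 12 and 1 adjusted over the list alone (adjusted p = 4.63e-12). Meiotic genes rose in 16 of 31, 18 adjusted over the list alone (adjusted p = 1.64e-07), and 11 of 17 pluripotency genes fell, Pou5f1 from 516 ± 59.4 to 174 ± 17.5 among them. BMP targets rose in 3 of 12, 4 adjusted over the list alone, without a list call (adjusted p = 0.796), and under quantile normalization 1 rose and 2 fell. Id1 was at 52.0 ± 16.1. Germ cell and piRNA genes rose in 9 (adjusted p = 3.83e-06, or adjusted p = 0.0659 with an estimated correlation). The somatic lineage list had 3 genes higher, Hoxa5 (23.8 ± 1.97 against 0.161 ± 0.227) among them, at adjusted p = 0.0083. Stress response genes rose in 3 of 7, Atf3 (17.0 ± 2.32 against 0.482 ± 0.682) among them (adjusted p = 0.0319, or adjusted p = 0.0739 with an estimated correlation), and fibroblast genes in 4 of 9 without a list call (adjusted p = 0.552). At day 5 of RA 29 genes were called, and 19 and 7 without CT replicates 1 and 2 and 9 without RA replicate 2. Mdk, a heparin-binding growth factor raised by retinoic acid (262 ± 35.3 against 37.7 ± 0.0548), and Cyp26a1 (42.4 ± 6.34 against 0.183 ± 0.259) were among them. At day 7 there were 619, falling to 368 without CT replicate 2 and to 230 without RA replicate 2. Rarb (25.5 ± 12.1 against 0.277 ± 0.0454) and Lefty1 (391 ± 16.4 against 80.8 ± 17.2) were higher then, and Entpd2 (5.48 ± 1.07 against 25.5 ± 5.88) lower.

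RB and RA differed in BMP targets from day 5 and in the meiotic list at days 7 and 9, while Stra8 was not called at day 9. At day 9 of the direct comparison Stra8 was 1447 ± 299 against 1094 ± 162 RPM (log2 fold change 0.40, adjusted p = 0.303). Sycp3 was at 1509.8 ± 23.5 against 52.2 ± 7.41 (log2 fold change 4.83, adjusted p = 5.53e-10), Rad51ap2 at 182 ± 8.98 against 2.13 ± 1.24, 4930528F23Rik at 176 ± 26.2 against 2.98 ± 1.13 and Mei1 at 31.1 ± 6.02 against 0.158 ± 0.223. Id1 was at 315 ± 34.7 against 52.0 ± 16.1. RB carried 1550 genes above RA and 1393 below (1442 and 1524 with median centring, 1637 and 1665 with quantile normalization). Zfp541 (106 ± 11 against 2.14 ± 1.87), the germ cell factor Dmrtc2 (215 ± 37.7 against 5.49 ± 1.52), Msx1as (54.1 ± 3.26 against 0.746 ± 0.282), Tex101 (702 ± 73.9 against 22.3 ± 7.5), Tex16 (143 ± 15.8 against 3.86 ± 1.89), the meiotic cyclin Ccnb3 (86.9 ± 11.1 against 1.94 ± 0.815) and Ccdc79 (79.8 ± 7.82 against 2.37 ± 2.46) were among the largest increases. The Nodal targets Lefty1 (26.5 ± 4.87 against 477 ± 68.3) and Lefty2 (10.4 ± 0.664 against 141 ± 30.7), the interferon-response genes Zbp1 (0.596 ± 0.842 against 23.7 ± 5.50) and Oasl2 (2.14 ± 0.774 against 29.5 ± 5.13), and Dcn of fibroblasts (1.99 ± 1.68 against 40.0 ± 12) were lower in RB. So were Car2 (5.18 ± 3.91 against 61.1 ± 1.76), Actg2 (3.98 ± 3.35 against 42.3 ± 8.61), Gprc5c (1.66 ± 0.455 against 24.1 ± 2.41), Clu (9.82 ± 8.58 against 78.4 ± 7.49) and Hesx1 (1.53 ± 0.486 against 21.5 ± 5.92). Meiotic genes were higher in 26 of 31 (adjusted p = 4.09e-19), germ cell and piRNA genes in 15 of 18, 16 adjusted over the list alone (adjusted p = 1.65e-10), and BMP targets in 9 of 12, 10 adjusted over the list alone (adjusted p = 7.67e-07). Pluripotency genes were lower in 12 and higher in 1 (adjusted p = 7.32e-09), Prdm14, a PGC specifier, at 10.2 ± 3.01 against 39.5 ± 1.44. Retinoic acid targets were lower in 6 of 13, Cyp26a1 and Dhrs3 among them, with adjusted p = 0.0147, or adjusted p = 0.0812 with an estimated correlation. Fibroblast genes were lower in 7 of 9 (adjusted p = 0.000277, or adjusted p = 0.102 with an estimated correlation), and stress response genes in 3 of 7 (adjusted p = 0.0419, or adjusted p = 0.0812 with an estimated correlation).

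Only 5 genes were called between RB and RA at day 5, all higher in RB: Id1 (37.5 ± 9.80 against 3.25 ± 2.07 RPM), Id2 (26.6 ± 0.720 against 9.80 ± 1.35), Zglp1 (7.78 ± 0.776 against 1.04 ± 1.06), Phlda2 (119 ± 27.3 against 35.6 ± 10.8) and Unc5b (log2 fold change 2.12, adjusted p = 0.00749), the last named after the values were seen. Without RB replicate 1 and without RA replicate 2 the count was 1, and without RB replicate 2 it was 2. Id2 lost its call without any 1 of the 4 libraries (adjusted p = 0.0538 to 0.95) and Zglp1 without any but RA replicate 1 (0.143 to 1.0). Phlda2 lost it without RB replicate 1 (0.129) and RA replicate 2 (0.636), and Id1 lost it with only the groups compared in the fit (0.773). Deviations from the group mean in libraries of the same replicate number had a correlation of 0.698 between RB and RA at day 5. The unpaired test does not remove such shared deviations. BMP targets as a list were higher at camera adjusted p = 1.71e-10. At day 7 the call covered 549 genes. Of these 233 and 226 stayed called without RA replicates 1 and 2, and 102 without RB replicate 2. Id1 (247 ± 45.8 against 11.2 ± 9.05), Lhx2 (61.9 ± 3.85 against 2.47 ± 2.23), Tsc22d3 (32.5 ± 13.4 against 1.25 ± 0.335) and Tex12 (73.2 ± 16 against 5.63 ± 1.28) were higher in RB and the keratin Krt7 (2.70 ± 1.55 against 23.4 ± 7.01) lower. Meiotic genes were higher in 21 of 31 and in 25 adjusted over the list alone (adjusted p = 2.26e-20). Stra8 (log2 fold change 1.05, adjusted p = 0.0326) lost its call without RA replicate 1 (adjusted p = 0.341), RB replicate 1 (0.0503) and RB replicate 2 (0.346).

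**Figure D3:**
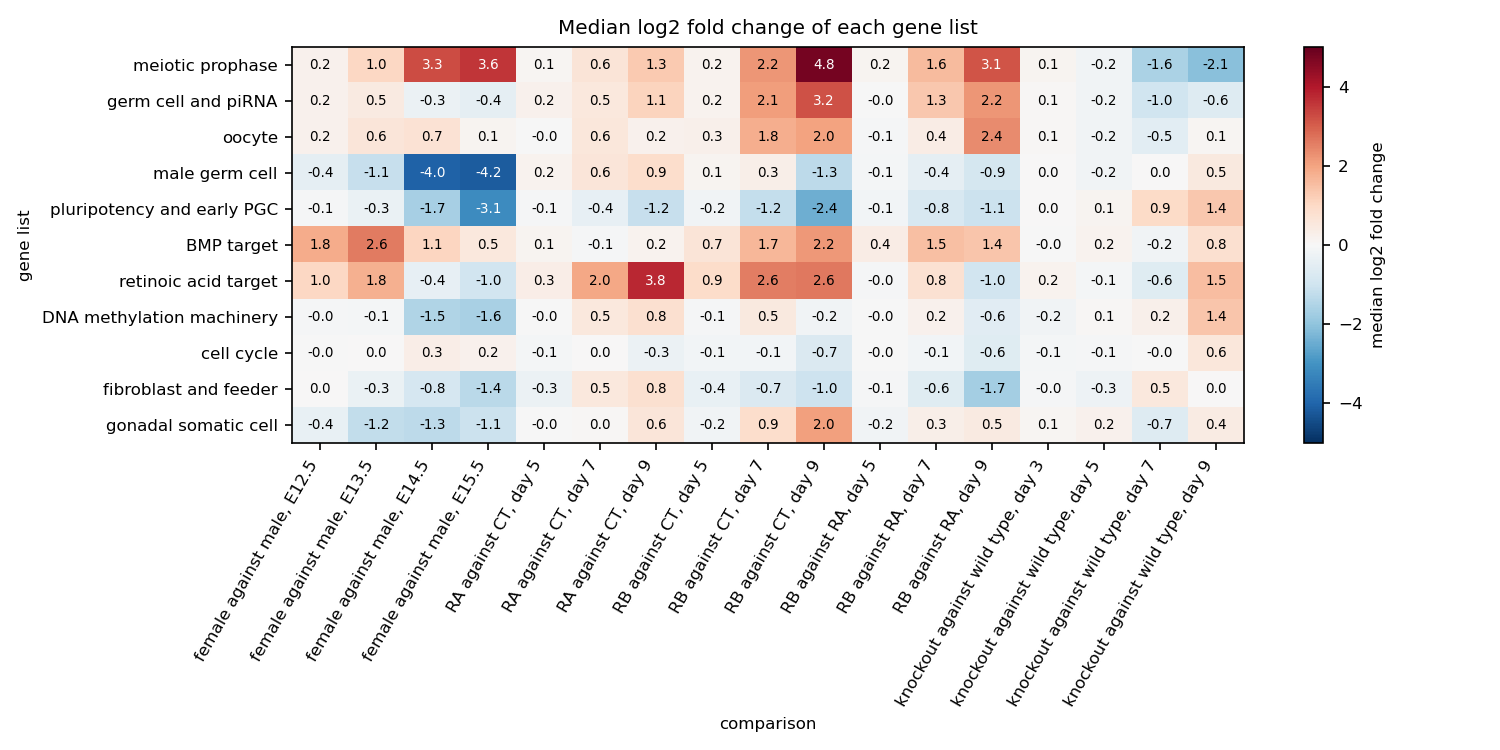
Median log2 fold change of 11 gene lists in 17 comparisons. The meiotic prophase list has a median of 4.79 for RB against CT at day 9, 3.25 for female against male at E14.5 and -2.10 for knockout against wild type at day 9.

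In the Stra8 knockout at day 9 of RB, most meiotic genes were lower than in the wild type, and pluripotency and retinoic acid target genes were higher. Rad51ap2 was at 0.408 ± 0.619 RPM in the knockout (n = 4) and 167 ± 81.8 in the wild type (n = 2; log2 fold change -6.90, adjusted p = 1.99e-13), Prdm9 at 3.0 ± 0.672 against 72.5 ± 1.91, and Msh5, of crossover formation, at 3.40 ± 1.34 against 72.2 ± 13.1. Nanog was at 66.3 ± 10 against 18.0 ± 10.2 and Hoxb1, a retinoic acid target, at 40.2 ± 11.9 against 1.12 ± 0.400. Of 12206 genes 1316 rose and 1019 fell (1153 and 1181 with median centring, 1267 and 1300 with quantile normalization). The lipid regulator Pparg (1.81 ± 1.6 against 89.5 ± 7.85), D6Mm5e (19.7 ± 5.66 against 476 ± 2.35), Tc2n (5.33 ± 2.43 against 125 ± 26.6), BC051142 (4.38 ± 3.25 against 94.7 ± 27.0), Spdya (10.1 ± 2.15 against 199 ± 35.7), Zcwpw2, a histone reader (1.5 ± 1.12 against 39.5 ± 14.3), and the amylase gene Amy1, which has near-identical copies (1.00 ± 0.223 against 35.7 ± 10.1), were among the largest decreases. Krt8 (28.9 ± 4.81 against 0.654 ± 0.262) and Krt18 (96.9 ± 24.8 against 8.13 ± 1.56) of simple epithelia, Dnmt3l (54.1 ± 18.2 against 2.53 ± 2.39), Sohlh1 (38.9 ± 6.95 against 1.82 ± 1.39), the lipase Lipc (29.6 ± 7.27 against 1.07 ± 0.856), Oasl2 (44.3 ± 14.8 against 2.2 ± 0.456), Tgfbi (46.1 ± 7.5 against 2.90 ± 0.537), Cpm (37.7 ± 7.30 against 2.76 ± 2.72) and Ptgr1 (289 ± 46.4 against 26.5 ± 0.453) rose most. Meiotic genes fell in 27 of 31 (median -2.10, adjusted p = 3.3e-18). Stra8, the gene knocked out, is a member of this list and among the 27, and it was not taken out of the list tests. Of the 4 not called, Rec8 stood at 432 ± 66.7 against 265 ± 15.2 (log2 fold change 0.70), Mnd1 at 122 against 85.7, 2410076I21Rik (Rec114) at 71.5 against 84.1 and Psmc3ip at 62.8 against 68.9.

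Pluripotency genes rose in 14 of 17 (adjusted p = 8.86e-10), Esrrb at 59.3 ± 13.7 against 12.3 ± 2.81 among them. Retinoic acid targets rose in 9 of 13 (adjusted p = 6.85e-05), and DNA methylation genes in 5 of 8 (adjusted p = 0.000629), such as Tet1 at 60.8 ± 13.2 against 19.8 ± 2.85. BMP targets rose in 5 (adjusted p = 0.0127, or adjusted p = 0.152 with an estimated correlation), with Id1 at 749.7 ± 44.2 against 232 ± 15.9. The cell cycle list had 4 genes higher, Plk1 at 168 ± 24.7 against 76.0 ± 4.15 among them (adjusted p = 0.00582, or adjusted p = 0.112 with an estimated correlation). Germ cell and piRNA genes fell in 6 and rose in 1 (adjusted p = 0.000285), with Tex15 at 203 ± 31.7 against 1144 ± 100.3, and male germ cell genes rose in 5 (adjusted p = 0.0127). The difference appeared late. At day 3, 372 genes had unadjusted p < 0.05 by limma, fewer than chance alone gives, which holds for each such number given below. Of these 1 gene was called, D10Bwg1379e with log2 fold change 2.00 and adjusted p = 0.0486, named after the values were seen. The count was 0 without wild type replicate 2 and without SK1_1, SK1_2, SK2_1 or SK3_1, and 5 other genes without wild type replicate 1. At day 5 Stra8 (log2 fold change -4.80) and the lactate dehydrogenase gene Ldha (44.4 ± 17.1 against 174 ± 35.0) were called, with 5 called without SK1_1. Without wild type replicate 2 the count was 1 and Ldha had adjusted p = 0.124. At day 7 there were 1066, with meiotic genes lower in 23 of 31, 24 adjusted over the list alone (adjusted p = 1.09e-17), Tex11 at 4.36 ± 0.669 against 35.4 ± 4.95, Tro at 0.982 ± 1.1 against 23.2 ± 0.102, and D6Mm5e at 8.30 ± 1.23 against 91.5 ± 0.401. Glipr2 (107 ± 14.6 against 21.2 ± 3.85) and Chga (31.4 ± 5.46 against 6.05 ± 1.69) were higher. The knockout effect changed between days 3 and 9 for 1814 genes, Rad51ap2 with a log2 difference of -7.17 among them.

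The genes raised by RB at day 9 were largely genes that rose in female germ cells by E15.5. Of the 2750 tested in the embryo, 2256 (82 %) were called higher in E15.5 females against E11.5, compared with 9.9 % of other genes. In E15.5 males against E11.5 it was 1294 (47.1 %, against 16.8 % of other genes). Of the same 2750 genes 1428 (51.9 %, against 13.9 % of other genes) were called higher in females than males at E14.5. The same 1428 genes were 54.5 % of the 2622 genes higher in E14.5 females and tested in PGCLCs. Of other genes 15.1 % rose with RB. Of the 2622 genes 498 (19 %, against 9.8 % of other genes) rose with RA. In RB 948 (36.2 %, against 6.5 % of other genes) were higher than in RA. The list of female genes passed for RB against CT (adjusted p = 8.03e-25, or adjusted p = 0.000855 with an estimated correlation) and for RA against CT (adjusted p = 3.15e-05, or adjusted p = 0.0801 with an estimated correlation). Of the list, the genes with a log2 difference of at least 2 passed for RA also with an estimated correlation (adjusted p = 0.0396). In the knockout at day 9, 816 genes raised by RB (28.9 %, against 1.5 % of others) were lower. The whole RB list had a median log2 fold change of -0.64. Of the female genes 678 (25.7 %, against 3.4 % of other genes) were lower. Of the genes lower in E14.5 females than males 607 (22.6 %, against 5.8 % of other genes) were higher. That last list holds early PGC genes such as Dppa4 beside male germ cell genes, so it does not mark the male fate alone. Sycp3, Sycp1, Tex101 and Rad51ap2 are members of the RB list. These lists come from samples of the same series, so their overlap is not independent evidence.

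The ranking used the 10266 genes called in any embryo comparison, so the genes were chosen on these embryo libraries. RB at day 9 lay closest to female germ cells at E14.5, with Spearman rho 0.929 (0.721 for E14.5 males). Day 0 PGCLCs lay closest to E10.5 (0.949), CT at day 9 to E11.5 (0.948), RA at day 9 to E12.5 females (0.893, with E13.5 females at 0.890) and RB at day 7 to E13.5 females (0.933). RA at day 7 was near E12.5 females (0.924) and E11.5 (0.923) alike. In the Stra8 experiment, the wild type was closest to E13.5 females at day 7 and E14.5 females at day 9 (0.920 each), and the knockout to E12.5 females at day 7 (0.920) and to E13.5 females at day 9 (0.904).

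**Figure D4:**
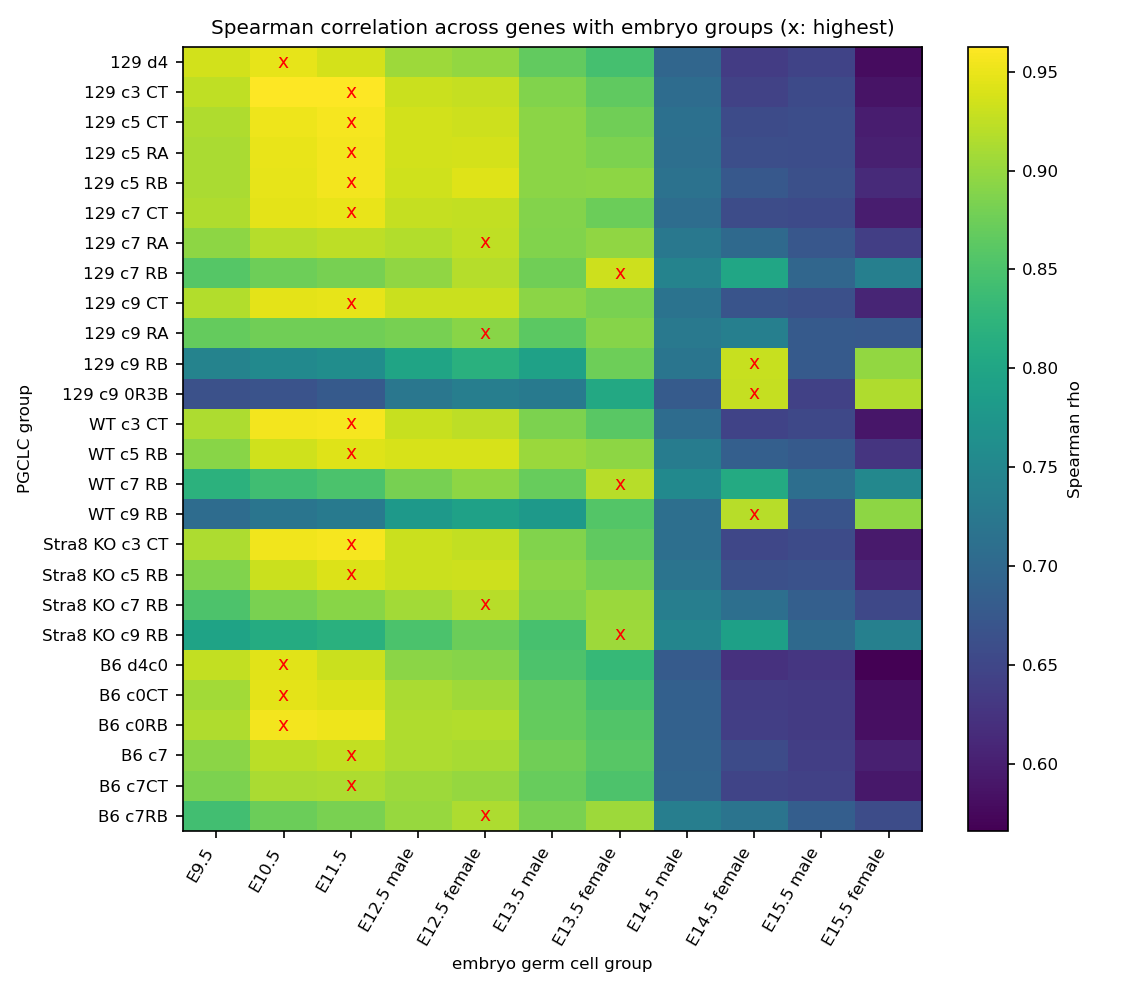
Spearman rho of each PGCLC group with each embryo group, with a cross at the highest. RB at day 9 peaks at 0.929 with E14.5 females, and the knockout at day 9 at 0.904 with E13.5 females.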

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

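Of the tests below, those on mixing, on counting error, on SK3 at day 5, on genes stable within both hybrid lines and on day 3 against day 9 were chosen only after the results were seen. Predictions for the first test of line identity, for spike-in within libraries and for depth were written before. The fit with spike-in as a term and the thinning used for depth were themselves alternatives chosen after seeing the data.

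In the knockout at day 7, Stra8 was at 204.13 RPM in the SK3 library and at 29.3 to 33.3 in the other 3 knockout libraries, a library far from the others. On the log2(RPM + 1) scale it was the only one of 88 combinations of gene and group of 4 libraries that lay that far out. Chance gives about 1 in 20, so a count of 1 in 88 is no more than chance gives. That count pools many genes, so it does not weigh whether Stra8 was high in SK3 again at day 9. At day 9, SK3 stood at 483 RPM and the others at 77.9 to 122. Mixing of wild type cells into SK3 would move the 942 genes lower in the other knockout libraries 22.9 % of the way to wild type at the level of Stra8. Their median was at -1.07 % (interval -2.06 to -0.3), which argues against mixing. The lower end of the counting interval of SK3 at day 9, 445.8 RPM, lies above 122, which argues against counting error. Days 7 and 9 prompted the idea of a stable difference between lines in reads from the Stra8 locus, so only day 5 tests it. There SK3 had 11 RPM with a lower interval end of 7.5, and the interval of the highest other library reached 14.8, so this stays open. The labels do not give the deleted part, each of SK2 and SK3 has 1 library per day, and this pattern was found and tested on the same libraries.

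The effect of a factor differed between times in each of the 3 tests of a difference. RB against CT changed between day 5 and day 9 for 3530 genes (2397 higher at day 9, such as Tex101, and 1133 lower, such as Nanog; 1623 and 1951 with median centring, 1705 and 1954 with quantile normalization). Female against male changed between E12.5 and E15.5 for 6277 genes (2794 higher, 3483 lower; 2973 and 3349 with median centring, 3165 and 3088 with quantile normalization), and knockout against wild type between day 3 and day 9 for 1814 genes (1057 higher, 757 lower, such as Rad51ap2 and Prdm9; 846 and 946 with median centring, 1017 and 976 with quantile normalization). The direction of the majority turned under both scalings for RB, under quantile normalization alone for the sexes and under median centring alone for the knockout. Day 3 had CT and day 9 had RB, so time and factor change together in the last of these. The sorting reporter changed between E12.5 and E15.5, so stage and reporter change together in the female against male contrast.

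For the knockout at day 9, technical explanations were set against a role of Stra8. Some libraries hold spike-in RNA and others do not. The 804 genes called lower in the libraries without it had a median log2 fold change of -1.27 (interval -1.31 to -1.23) within the libraries with it, and 99 % had the same sign. At day 9 the set with spike-in holds 1 library of each genotype, and the set without it holds 1 wild-type library. The interval is over genes, so alone this comparison excludes nothing. With spike-in as a term in the fit of all 24 libraries, 2395 genes were called, 2279 of them among the 2335, which argues against spike-in as the cause. With all libraries thinned to the shallowest, 2091 genes were called beside 2335, which argues against depth. Over 2334 genes called at day 9, the median ratio of the day 3 to the day 9 difference was 0 (interval -0.003 to 0.004), which argues against differences of the cell lines present before RB as the whole cause. A role of Stra8 remains as a hypothesis, and differences between lines that show only under RB were not tested apart from it.

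The single 0R3B library at day 9 had Stra8 at 2711.36 RPM, above the 6.75 to 8.08 of the CT libraries of that day. In the C57BL/6 line, the RB library of day 9 (c7RB) had Cyp26a1 at 191.91 RPM beside 17.37 under CT (c7CT). Rec8 was at 133.73 beside 12.1 and Id1 at 278.08 beside 24.81. RB in this line may have started on another day than in the other lines, so its length by day 9 need not match theirs. These signals lie in libraries that no comparison uses.

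In that same C57BL/6 library Stra8 was at 27.5 RPM beside 24.5 under CT, while RB at day 5 gave at least 44.6 in the other lines with Stra8 intact. The upper end of its counting interval, 33.1, lies below 44.6, which argues against counting error. Over 88 genes that separate the other C57BL/6 from the DBA/2:C57BL/6 libraries it lay at 3.1 % of the way from the DBA/2:C57BL/6 mean, but RB libraries of the 129S1:C57BL/6 line lay at -9.4 and -16.5 % and CT ones at 68.9 and 70.4 %, so these genes follow RB and decide nothing. Over 9 genes stable within both hybrid lines it lay at 4.8 % (interval -1.1 to 13), where held-out C57BL/6 libraries lay at 87.3 to 110.1 % and DBA/2:C57BL/6 libraries at -12.2 to 14.2 %. An example is Gm15682, at 190 RPM in this library, 33.9 in the other C57BL/6 and 198 in the DBA/2:C57BL/6 libraries. This library alone of the 6 of its line lacks spike-in RNA (9.2 RPM, with 21050 to 38040 in the other 5), as 14 of the 24 DBA/2:C57BL/6 libraries do. A wrong line label may therefore be a candidate explanation. Its Stra8 lies near 3 of the 4 knockout libraries of day 7 (29.3 to 33.3), and no DBA/2:C57BL/6 library lies on the C57BL/6 side. A difference of the line or its schedule cannot be told apart from this with 1 such library, and its values are best read with that doubt.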

How the results depend on the processing

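Of the alternatives, thinning, the 2 on spike-in and the one on libraries of at least 1.5 M reads were chosen after seeing the data; all were run. Counts are of called genes, within 1.5 times the reported count unless given here, and for all counts below the cause was not tested unless the construction shows it.

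Under log2(RPM + 5), which shrinks the fold changes of low genes, 13 of 24 counts stayed within 1.5 times. The others were 365 at E12.5 and 1126 at E13.5 between the sexes, 1287 for RB against CT at day 7, 292 and 1098 for RA against CT at days 7 and 9, 307 for RB against RA at day 7, 338 for day 3 against day 0, 155 for CT day 9 against day 3, and 0, 460 and 1466 for the knockout at days 3, 7 and 9. The filter at 20 RPM tests fewer genes, and 15 of 24 counts stayed. The others were 539 at E12.5, 1325 at E13.5, 1353 (RB day 7), 403 and 1063 (RA days 7 and 9), 406 (day 3 against day 0) and 0, 646 and 1523 (knockout days 3, 7 and 9). Without a filter the counts were 37 (RB day 5), 19 (RA day 5), 2 (RB against RA day 5), 159 (CT day 9 against day 3) and 6 (knockout day 5). For the knockout at day 3 the count stayed at 1 without a filter, but it was another gene, lower in the knockout. Having only the groups compared in the fit leaves fewer degrees of freedom and also fewer genes tested. The counts were then 22 (RB day 5), 4 (RA day 5), 0 (RB against RA day 5, with 374 by limma at unadjusted p < 0.05 in the full fit) and 2 (knockout day 3).

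The 1 gene of the knockout at day 3 was lost (0 genes) with quantile normalization, thinning and the mean of the SK1 libraries, and 4 were called in libraries without spike-in. At knockout day 5 the counts were 7 with all 75 libraries in 1 fit, 6 with the mean of the SK1 libraries, 4 with thinning, 4 with libraries of at least 1.5 M reads and 0 in libraries without spike-in (adjusted p = 0.11 for Stra8 and for Ldha by limma, 537 genes at unadjusted p < 0.05 in the full fit), where day 7 gave 589. Each day has 1 wild-type library without spike-in, so the counts in libraries without spike-in rest on 1 wild-type library. Gata6 at knockout day 7 turned from 1.48 to a log2 fold change of -0.075 in libraries without spike-in. At day 7 these are the same libraries as those of at least 1.5 M reads, so the 2 alternatives give the same fold changes there. The libraries of other days differ between the 2 fits, so the calls differ. Median centring left all 24 total counts within 1.5 times, the spike-in as a term all 5, quantile normalization and all 75 libraries in 1 fit 23 of 24 each, and thinning 22. The split into higher and lower genes did move with the scaling, which shifts all genes of a library against another. The higher share for RB against CT went from 81.2 to 60.2 % (median centring) and 50.9 % (quantile normalization) at day 7 and from 66.9 to 48.5 and 46.9 % at day 9. For RA at day 9 it went from 81.6 to 61.1 and 51.4 %, for male E15.5 against E11.5 from 60.7 to 53.6 and 48.4 %, and for the knockout from 36.2 to 51.3 and 53.8 % at day 7 and from 56.4 to 49.4 and 49.4 % at day 9. With a block by replicate number (replicate block), a reading the labels do not give, all 24 counts stayed within 1.5 times. Of 733 values of named genes 729 kept their side of the threshold. The block is the same for all days and treatments, so it cannot remove deviations shared only within a day. Pairing within a day was not tested. In the 129S1:C57BL/6 line shared deviations were strongest at day 5 (correlations 0.544 to 0.698).

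Leaving out each library in turn, where the lone library is assumed to vary like the other groups, moved these counts (lowest to highest): E12.5 504 to 726, RB day 5 21 to 58, RA day 5 7 to 21, RA day 7 230 to 420, RB against RA 1 to 7 at day 5 and 108 to 457 at day 7, day 3 against day 0 346 to 449, CT day 9 against day 3 104 to 163, and knockout 0 to 5 at day 3 and 1 to 5 at day 5. Of 3079 values of named genes 2766 kept their side of the threshold. Of 733 values, 645 did with log2(RPM + 5), 680 without a filter, 704 with quantile normalization, 715 with all 75 libraries in 1 fit and 717 with median centring. With thinning 706 of 730 did, and with only the groups compared 660 of 686. The share was lowest in libraries without spike-in and next in those of at least 1.5 M reads, where some comparisons have 1 wild-type library.

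With an estimated correlation the lists called were 3 for male E15.5 against E11.5, 2 and 5 for RB at days 5 and 7, 1, 1 and 4 for RA at days 5, 7 and 9, 4 and 4 for RB against RA at days 7 and 9, and 0 for CT day 9 against day 3 and for knockout day 5. Of the lists taken from another experiment, genes raised by RB in knockout day 5 then had adjusted p = 0.0746. Genes higher in E14.5 females had adjusted p = 0.176 and 0.0801 in RA at days 7 and 9 and 0.350 in CT day 9 against day 3, and genes lower in females 0.158 and 0.0696 in RA at days 7 and 9. Taken at an absolute log2 fold change of at least 2, the female lists passed in RB at day 5 (medians 0.022 and -0.113, adjusted p = 0.0471 and 0.0280), but not with an estimated correlation (adjusted p = 0.36 and 0.251).

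The best embryo stage was the same for each group by Pearson correlation and over all kept genes. Among the 5 replicated groups of day 9 its value moved by more than the replicate SD to 0.890 (RA) and 0.947 (CT) by Pearson, and over all kept genes to 0.905 (RA), 0.954 (CT), 0.938 (RB), 0.930 (wild type) and 0.916 (knockout). Of the other groups given, RB and wild type at day 7 moved to 0.929 and 0.917 by Pearson, and over all kept genes day 0 went to 0.956, RA and RB at day 7 to 0.933 and 0.940, and wild type and knockout at day 7 to 0.929 each. Depth limits low genes: in the shallowest library 3 reads are 2.78 RPM.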

Other observations

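The values on fibroblast genes and on replicate numbers in this part were chosen only after results were seen, and percentiles of single libraries compare genes, not libraries.

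The 0R3B library of day 9 lay closest to E14.5 females (Spearman rho 0.927). Against the mean of CT at day 9 its meiotic prophase list had a median log2 difference of 5.18, with 30 of 32 genes higher, and its pluripotency list -4.05, with 15 of 17 lower. Against RB at day 9 the meiotic median was 0.47 (percentile 99.94 of 10000 random lists matched on expression), the pluripotency median -1.52 (percentile 0) and the BMP target median -0.50 (percentile 0.81). Sycp3 stood at 2305 RPM, Sycp1 at 760, Rec8 at 302 and Id1 at 103, beside 1509.8 ± 23.5, 482 ± 61.3 and 315 ± 34.7 for Sycp3, Sycp1 and Id1 under RB.

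Of the C57BL/6 line, c7 against day 0 had a germ cell and piRNA median of 3.50, with 11 of 14 genes higher, and a BMP target median of -0.74. The RB library of day 2 exceeded its CT library in retinoic acid targets by a median of 1.99 (5 of 6 higher, percentile 100). In the day 9 libraries RB exceeded CT by 3.39 in retinoic acid targets (12 of 13 higher), 1.72 in meiotic genes (14 of 20), 0.97 in BMP targets (5 of 10, with 1 lower) and 1.21 in male germ cell genes (6 of 12, with 2 lower). The fibroblast and feeder list had a median of -1.05, with 5 of 9 genes lower. The doubt about the line label of that RB library, given above, holds for these values. Stra8 was at 0.462, 0, 0.270 and 1.07 RPM in the day 0, day 2 CT, day 2 RB and day 7 libraries.

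Fibroblast genes varied among cultured libraries. At day 9, Col3a1 was at 49.3 ± 27.0 RPM under RA, 27.9 ± 15.6 under CT and 12.6 ± 9.12 under RB, and Dcn at 40.0, 11.6 and 1.99. The call of Dcn for RA against CT (log2 fold change 1.72) gave adjusted p = 0.091 without CT replicate 2 and 0.0814 without RA replicate 2.

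Between groups, deviations from the group mean in libraries of the same replicate number had correlations from 0.072 to 0.698 in the 129S1:C57BL/6 line, from -0.064 to 0.273 in the Stra8 experiment and from -0.092 to 0.149 in the embryo. No label gives a reason.

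Xist was at most at 12.6 RPM in every library, too low to check sex, and Y-linked genes are not in the table used here. In the embryo the X-linked genes gave the values reported with the sexes.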
